A study of Mus musculus with 12 samples.

How the data were processed

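Total RNA from mouse liver was labelled with biotin by a one-cycle amplification and hybridised to Affymetrix arrays, 1 array per animal, per the labels' protocols. The 12 arrays fall into 4 groups of 3: control livers and livers with a hepatocyte knockout of Met, each without HGF and after HGF. Groups and replicate numbers were taken from the sample titles. The array numbers run from 1 to 6 for the controls and from 7 to 12 for the knockouts. Genotype therefore cannot be told apart from array order in any knockout contrast. The deposited values are probe set intensities on a linear scale, read as linear from the values themselves, which have a median of 6.75 to 7.03 and an upper quartile of 61.1 to 64.3 on every array. They were made with GCRMA, a method that corrects probe intensities for background by their base composition and normalizes between arrays, per the submitters' processing notes; its version is not given in the sources used here. GCRMA brings the arrays to a common distribution, so a change shared by most genes would not be visible in these values, and it compresses signals near background, where fold changes are uncertain.

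The table holds 16539 probe sets, of which 64 are array controls. Of the other 16475 probe sets, 15780 were paired with 1 gene symbol by the platform annotation and 695 with none. The annotation gives 1 probe set per gene, so no choice between probe sets of a gene was needed. A RefSeq gene table of the GRCm38.p6 assembly was used for current names, which changed 0 symbols, and for the order of neighbouring genes; no coordinates are given, as the build behind the array design is not stated.

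Values were put on the scale log2(intensity + 1), and all fold changes below are differences on that scale, which understates the change of genes near background. Probe sets were tested where the log2 value was at least 4 on at least 3 arrays, which left 6683 probe sets, 6427 of them with a gene symbol and 256 without. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups and 8 residual degrees of freedom, followed by empirical Bayes moderation. The 6 contrasts were the HGF effect in control livers, the HGF effect in knockout livers, the knockout effect without HGF and with HGF, the knockout effect averaged over both conditions, and the interaction. The interaction is the HGF effect in knockout livers minus that in control livers. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, with no limit on the fold. All tests were two-sided. The number of arrays, 3 per group, limits the precision; the median standard error of a log2 difference between 2 groups was 0.18, and that of the interaction was 0.25.

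Before the data were examined, the groups, the model, the filter, the alternatives, the rule for named genes and 35 gene lists were fixed. The rule named Met and Hgf and, in each contrast, the 12 called genes with the largest rise and the 12 with the largest fall of at least 1 on the log2 scale, without that limit where fewer than 5 passed. It further named up to 4 called members of each list and, where a contrast had few calls, the called genes and the 10 with the smallest p. It allowed any member of the lists of immediate early genes, ERK feedback genes and the HGF and Met pathway in the HGF contrasts, and up to 2 of the most abundant members of a list that did not shift. Genes outside the rule are members that passed when adjusted over their list alone or were chosen after their values were seen.

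The lists covered immediate early genes, ERK feedback, the HGF and Met pathway, the acute phase, NF-kappaB targets and chemokines, interferon targets, survival and apoptosis, NRF2 antioxidant genes, the cell cycle, p53 and growth arrest, bile acid metabolism, sterol synthesis, lipogenesis, and PPAR-alpha and fat oxidation. Others covered gluconeogenesis and insulin, the circadian clock, glucocorticoid and stress genes, xenobiotic metabolism, ER stress, heat shock, hypoxia, cytoskeleton and motility, and matrix and stellate cells. Cell type and zone lists covered cholangiocytes, Kupffer cells and macrophages, neutrophils, lymphocytes, sinusoidal endothelium, erythroid cells, pancreatic acinar cells, hepatocytes, pericentral and periportal hepatocytes, and genes with female-biased or male-biased expression in liver. A few genes stand in more than 1 list. Lists with at least 3 tested members were tested against all other tested genes with camera at its preset correlation of 0.01, with p adjusted over the lists of a contrast. Only 1 cholangiocyte, 1 lymphocyte, 1 acinar and 2 erythroid genes passed the filter, and these 4 lists were not tested. Camera with the correlation estimated from the data, and fry, a rotation test of whether the members of a list move on balance one way, were run as alternatives. Members were also adjusted over the list alone.

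The model was tested on simulated data with 200 of 6683 genes changed in each of 20 runs. For the HGF effect in control livers it called 70.2% of genes changed by 1 on the log2 scale, 91.8% of those changed by 2 and 97.1% of those changed by 3. For the HGF effect in knockout livers these shares were 69.4%, 91.7% and 96.7%; for the knockout effect without HGF 68.9%, 93.1% and 95.7%. For the knockout effect with HGF they were 68.5%, 90.5% and 97.4%; for the averaged knockout effect 85.2%, 96.3% and 98.5%; and for the interaction 46.3%, 81.1% and 93.6%. The simulation gave every gene the same kind of spread on all arrays and holds no array that stands apart from its group.

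Alternatives were no filter, a filter at log2 of 6, arrays centred on their medians, a further quantile normalization, an intensity trend with a robust prior, array weights, a fit on only the groups compared, and the replicate number as a fixed or random block. Further ones were each array left out in turn, the 2 arrays whose label has an added letter A left out, a 2-fold limit, a test against 1.2-fold, an offset of 16, and the other list tests. A fit without both knockout replicate 2 arrays and a fit with no offset were added after the data had been seen. Every result was recomputed under each alternative that could give a value. No column of the table was left without a sample, and no array was left out of the results as reported. The smallest standard deviation of the log2 difference between any 2 arrays was 0.282, so no array was a copy of another.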

Results

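Livers of 12 mice were profiled, 3 mice in each of 4 groups. Control mice carried loxP-flanked alleles of Met, the gene for the receptor of hepatocyte growth factor (HGF). Knockout mice had been bred to a Cre transgene under an albumin and alpha-fetoprotein promoter and enhancer, or under the albumin promoter, which removes the receptor from hepatocytes; the labels do not say which transgene each array represents. Each genotype was sampled without stimulation and 2 h after an intraperitoneal injection of 2 µg recombinant mouse HGF. The protocol names HGF or sodium chloride injections and a state before and after injection, so it stays open whether the unstimulated mice had been injected. If they had not, an effect of HGF cannot be told apart from one of the injection and handling. The HGF effect below therefore means the difference between the groups labelled with and without HGF. The series concerns the part that Met in hepatocytes plays in chronic liver damage after ligation of the bile duct, and these arrays address which liver transcripts respond to HGF and which of the responses need Met in hepatocytes.

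The arrays were alike in range: 37.9% to 38.4% of probe sets lay at or above a log2 value of 4, and Pearson's r between arrays across tested probe sets was 0.914 to 0.992. The first principal component held 62.3% of the variance and the second 11.2%. Each array was also placed on a response index over all tested probe sets, where the mean of the control arrays without HGF is 0 and that of the control arrays with HGF is 1. Control arrays lay at -0.06 to 0.07 without HGF and at 0.88 to 1.06 with it, a separation that the definition of the index favours. Knockout arrays labelled without HGF lay at 0.12, 0.98 and 0.04 for replicates 1 to 3, and those labelled with HGF at 0.32, 0.02 and 0.94. On this index, knockout replicate 2 without HGF thus stood at the level of the HGF-treated controls, and knockout replicate 2 with HGF at that of the untreated controls. Over only the genes called for HGF in controls, knockout replicates 1 to 3 lay at 0.53, 0.86 and 0.44 without HGF. They lay at 0.69, 0.43 and 0.84 with HGF, against -0.03 to 0.05 in untreated controls. Those genes were chosen for their difference between the control groups against a spread pooled over all 4 groups. Genes that varied widely between knockout arrays were thus less likely to be called. The choice favours knockout arrays that lie close together, so these middle values do not show a partial response in untreated knockouts. All values below follow the labels as given, and the count of genes in each knockout comparison, with the list calls that begin or end, is also given without these 2 arrays, a choice made after the arrays had been compared.

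**Figure D1:**
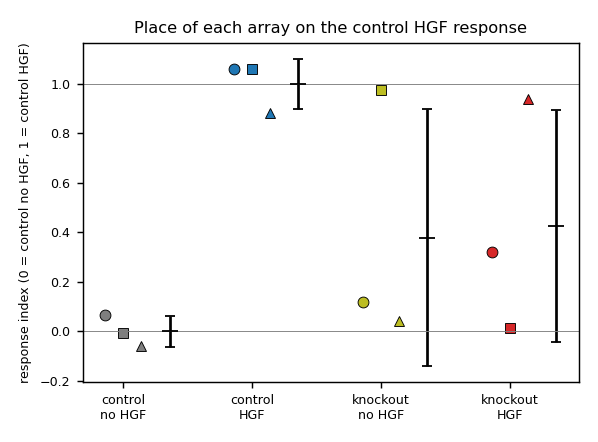
Response index of the 12 arrays, in units of the mean HGF response of the control livers over all tested probe sets, with horizontal lines at 0 (mean of controls without HGF) and 1 (mean of controls with HGF). Points are arrays, the marker gives the replicate number, and bars are means with SD (n = 3); the knockout arrays without HGF lie at 0.12, 0.98 and 0.04 and those with HGF at 0.32, 0.02 and 0.94.

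Met transcript was not lower in the knockout arrays. The Met probe set (Entrez Gene 17295) had log2 intensities of 6.74 ± 0.11 in control livers without HGF, 6.80 ± 0.21 in controls with HGF, 6.98 ± 0.26 in knockouts without HGF and 6.77 ± 0.57 in knockouts with HGF (SD, n = 3). The averaged knockout effect on Met was 0.10 (SE 0.18, limma adjusted p = 0.872). Which part of the transcript the probes cover is not known here, and probes outside the deleted part check nothing, so these values neither check nor contradict the genotype labels. The Hgf probe set (Entrez Gene 15234) stayed below the filter, with means of 3.52, 3.38, 3.93 and 3.58 in the same order of groups.

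In control livers, Mt1, Junb and Plk3 had the largest rises called by limma 2 h after HGF. The metallothionein gene Mt1, which binds metals and responds to stress and glucocorticoids, rose by 7.01 (SE 1.25, 129-fold), from 5.03 to 7.06 on the arrays without HGF to 12.71 to 12.97 on those with it. Junb, an AP-1 subunit, rose by 4.46 (SE 0.69) and Atf3, a stress-induced transcription factor, by 2.79 (SE 0.47). The kinase gene Plk3 rose by 3.88 (SE 0.58), Nrg4, which encodes a ligand of ErbB receptors, by 3.11 (SE 0.44), and Phlda1 by 2.29 (SE 0.34). Among the falls were Cyp2c55, a cytochrome P450 gene, at -2.61 (SE 0.45), the mismatch repair gene Pms1 at -1.72 (SE 0.30) and Nme6 at -1.22 (SE 0.16). These 9 genes had limma adjusted p between 0.0338 (Junb) and just under 0.05 (Mt1 and Pms1).

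Limma called 27 genes for the HGF effect in control livers, 20 up and 7 down, and 19 of them changed at least 2-fold. Other called rises were those of Csrnp1 (2.31), Bach1 (1.65), a repressor of antioxidant genes, 1810055G02Rik (1.47), Sh2d4a (1.46), Trib1 (1.36), Klf7 (1.29) and the dioxin receptor gene Ahr (0.62). Other called falls were those of Saysd1 (-0.75), Rai14 (-0.74), Pgm3 (-0.72) and Top3b (-0.70). At an unadjusted p under 0.05 there were 1268 tested genes with a symbol, 575 of them higher with HGF. In 37.8% of genes the 3 arrays with HGF did not overlap the 3 without, against 10% by chance.

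The lists of immediate early genes and of NF-kappaB targets had a positive change in every tested member. For the 18 immediate early genes, which answer growth factors and stress without new protein synthesis, the median was 2.39 (camera adjusted p = 1.1e-16), and 15 rose when adjusted over the list alone, against 2 over all genes. Their largest changes were Gadd45g (6.10), Ier3 (4.57), Junb (4.46) and Gadd45b (4.27). For the 16 NF-kappaB targets and chemokines the median was 3.79 (camera adjusted p = 2.5e-15), and all 16 rose when adjusted over the list alone while 0 passed limma over all genes. They included Tnfaip3 (7.83, SE 2.07), a feedback inhibitor of NF-kappaB, the neutrophil chemokine genes Cxcl2 (7.73, SE 2.06) and Cxcl1 (6.05, SE 1.38, adjusted p = 0.0801 over all genes) and the adhesion gene Icam1 (6.60, SE 1.98). Both lists had an adjusted p = 0.292 with an estimated correlation.

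All 24 genes of the acute phase list, most of which encode proteins that hepatocytes secrete in inflammation, had positive changes. Their median was 1.10 (camera adjusted p = 1.9e-08, and adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 1 of the 24 rose, Socs3, by 4.04. Socs3 is a feedback inhibitor of cytokine signalling and not a secreted protein, while the secreted Saa3 (4.66, SE 1.65) and Lcn2 (5.46, SE 2.03) did not pass. Glucocorticoid and stress genes had a median of 1.68 with 9 of 11 positive (adjusted p = 1.2e-05), and 7 rose over the list alone, among them Mt2 (8.86) and Errfi1 (1.06). Interferon targets had a median of 0.80 with 14 of 17 positive (adjusted p = 2.5e-05), and 1, Irf1 (3.84), rose over the list alone. With an estimated correlation these lists had adjusted p = 0.292 for glucocorticoid and stress genes and adjusted p = 0.408 for interferon targets. The median of glucocorticoid and stress genes was 1.01 without control replicate 1 with HGF, and that of interferon targets 0.53 without control replicate 3 without HGF.

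Camera also called upward shifts for survival and apoptosis genes (median 0.49, adjusted p = 0.00341), neutrophil genes (3.39, adjusted p = 0.00341) and cytoskeleton and motility genes (0.17, adjusted p = 0.00341). It did so for ERK feedback genes (1.06, adjusted p = 0.0336), of which only 3 of 15 were tested, and matrix and stellate cell genes (0.18, adjusted p = 0.0450). Adjusted over the list alone, 3, 3, 4, 2 and 2 of their members rose, among them Birc2 (2.92), the neutrophil calcium-binding gene S100a9 (5.60), Rhob (3.33), Phlda1 and the basement membrane collagen gene Col4a1 (1.70). The matrix gene Lum (-0.78) fell, and the ERK feedback gene Dusp6 was lower with HGF (-0.88). Sinusoidal endothelial genes shifted down (median -0.37, 11 of 12 negative, adjusted p = 0.0199); 5 fell over the list alone, among them Gpr182 (-0.91) and Fcgr2b (-0.82), while Lyve1 rose (2.61). The matrix call ended without control replicate 2 or 3 without HGF, control replicate 1 or 3 with HGF, knockout replicate 2 without HGF or knockout replicate 3 with HGF (matrix medians 0.15 to 0.19), and the median was 0.29 without control replicate 1 without HGF. That of cytoskeleton genes was 0.11 without control replicate 3 with HGF. The endothelial call ended without control replicate 1 with HGF (-0.27) and the ERK feedback call without knockout replicate 3 with HGF (1.06). With camera on the 2 control groups alone, the ERK feedback (adjusted p = 0.181), matrix (0.0798) and endothelial (0.0513) calls ended as well. None of these 6 lists held with an estimated correlation, where the ERK feedback and survival lists had adjusted p = 0.292, the neutrophil, matrix and endothelial lists adjusted p = 0.335 and the cytoskeleton list adjusted p = 0.432.

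The other lists were not called for the HGF effect in control livers. Their medians were 0.81 for p53 and growth arrest (adjusted p = 0.0676), 0.08 for ER stress (0.0594), 0.21 for heat shock (0.0676), 0.10 for hypoxia (0.0901), -0.24 for xenobiotic metabolism (0.113) and 0.28 for gluconeogenesis and insulin (0.168). They were -0.41 for sterol synthesis (0.168), -0.16 for bile acid metabolism (0.366), -0.54 for the cell cycle (0.390), -0.30 for male-biased genes (0.149) and -0.11 for pericentral genes (0.353). The medians for the HGF and Met pathway, hepatocyte, circadian, lipogenesis, fat oxidation, NRF2, Kupffer cell, periportal and female-biased lists were -0.05, -0.05, -0.14, -0.06, -0.05, -0.17, -0.21, -0.16 and -0.06, with adjusted p of 0.770 to 0.985. Median, mean and test differed in sign for the lipogenesis, fat oxidation, NRF2, Kupffer cell and female-biased lists. Within these lists, the glucose-6-phosphatase gene G6pc fell by 3.65 and Igfbp1 rose by 3.54 when adjusted over the list alone, as did Hmox1 (4.02) and Gadd45a (1.81).

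The count of 27 rested on a spread pooled over all 4 groups: limma called 771 genes (437 up, 334 down) with the 2 control groups alone, 526 without the 2 knockout replicate 2 arrays and 1309 with array weights. Each of these counts included all 27. It called 13 with no filter and 0 with a replicate block, a random block, a test against 1.2-fold or the arrays with an added letter left out. It fell to 0 without control replicate 1, 2 or 3 without HGF or control replicate 2 or 3 with HGF and to 3 without control replicate 1 with HGF. It was 305 without knockout replicate 2 without HGF, 57 without knockout replicate 2 with HGF and 115 without knockout replicate 3 with HGF.

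**Figure D2:**
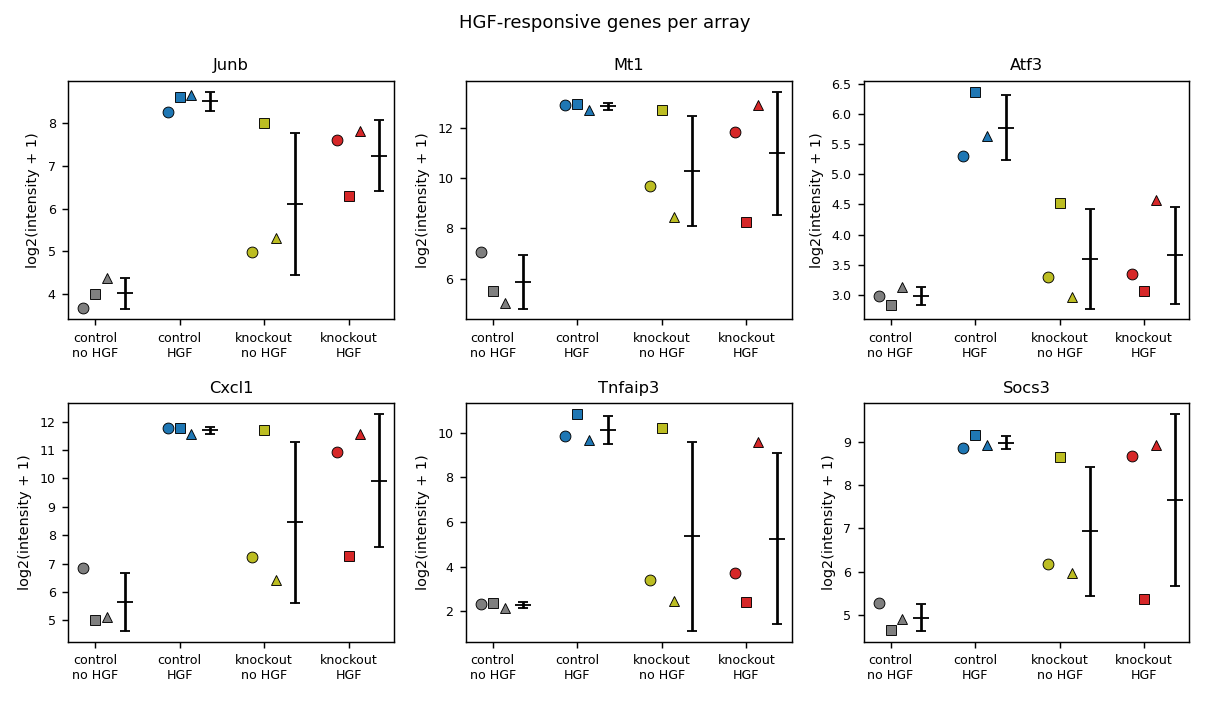
Log2(intensity + 1) of Junb, Mt1, Atf3, Cxcl1, Tnfaip3 and Socs3 on each array, by group. Points are arrays, the marker gives the replicate number, and bars are means with SD (n = 3); Junb lies at 8.24 to 8.64 in controls with HGF against 3.68 to 4.39 without.

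In knockout livers, the genes that rose with HGF in controls were high on some arrays of each group. Tnfaip3 was at 3.41, 10.22 and 2.45 without HGF (replicates 1 to 3) and at 3.74, 2.44 and 9.59 with HGF. Cxcl1 was at 7.23, 11.70 and 6.42 without HGF and at 10.94, 7.26 and 11.58 with HGF. The groups labelled with and without HGF therefore differed little in their means: the HGF effect was 1.13 for Junb, 0.06 for Atf3 and 0.72 for Mt1, none past the threshold.

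Limma called 0 genes for the HGF effect in knockout livers, with 120 tested genes with a symbol at an unadjusted p under 0.05 and a smallest adjusted p of 0.931. The smallest p belonged to Mgp, an inhibitor of calcification, at -1.47 (SE 0.27, adjusted p = 0.931), followed by Ttc39b (-0.49), Usp46 (-0.57), Smpd2 (-0.47), Slc3a1 (1.49) and the collagen gene Col3a1 (-0.91), all not past the threshold. In 3.72% of genes the groups did not overlap, against 10% by chance. Camera called small shifts for lipogenesis (median 0.33, 10 of 11 positive, adjusted p = 0.0229) and Kupffer cell genes (0.17, 16 of 16 positive, adjusted p = 0.0228). It also called male-biased genes (0.13, 9 of 9 positive, adjusted p = 0.0387) and pericentral genes (-0.10, 10 of 11 negative, adjusted p = 0.0187). None held with an estimated correlation, where lipogenesis and Kupffer cell genes had adjusted p = 0.945, male-biased genes adjusted p = 0.924 and pericentral genes adjusted p = 0.798. Limma passed 0 members of any list when adjusted over the list alone. Each of the 4 calls ended when single knockout arrays were left out. That of lipogenesis ended without replicate 2 (median 0.25) or 3 (0.38) without HGF or replicate 2 (0.11) or 3 (0.28) with HGF, and that of Kupffer cell genes without replicate 1 (0.08) or 2 (0.17) without HGF or 1 (0.03) with HGF. That of male-biased genes ended without replicate 1 (0.14) or 3 (0.16) without HGF or 1 (0.12) or 2 (0.11) with HGF, and that of pericentral genes without replicate 3 without HGF (-0.06) or 2 with HGF (-0.08). Where the calls held, the median of lipogenesis was 0.55 without replicate 1 with HGF, and that of Kupffer cell genes 0.29 without replicate 3 without HGF and 0.32 without replicate 2 with HGF. The median of male-biased genes was 0.20 without replicate 2 without HGF and 0.25 without replicate 3 with HGF. That of pericentral genes was -0.19 without replicate 1 of either group and -0.16 without replicate 2 without HGF. Immediate early genes had a median of 0.17 (adjusted p = 0.0708) and NF-kappaB targets of 0.08 (adjusted p = 0.644). No planned setting called a gene, whichever array was left out; without both knockout replicate 2 arrays, limma called 267 genes, 136 up and 131 down.

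Without those 2 arrays, the knockout HGF effect held inflammatory and clock genes. Cxcl1 rose by 4.43 (SE 0.56), Mt1 by 3.31 (SE 0.65), Socs3 by 2.72 (SE 0.21) and Junb by 2.55 (SE 0.24), and Egr1, an immediate early gene, by 4.01 (SE 0.86). The clock output genes Dbp (-6.77, SE 0.93), Ciart (-3.39, SE 0.28) and Tef (-3.20, SE 0.39) and the bile acid synthesis gene Cyp7a1 (-2.91, SE 0.52) fell, while the core clock gene Arntl rose by 2.85 (SE 0.24). Camera called upward shifts of immediate early genes (median 1.16), acute phase genes (1.06) and NF-kappaB targets (2.51), which had adjusted p = 0.400, 0.414 and 0.424 with an estimated correlation. It also called interferon targets (1.12, adjusted p = 4.3e-06), glucocorticoid and stress genes (1.16, 0.000544), heat shock genes (0.73, 0.000544), cytoskeleton genes (0.34, 0.000937) and neutrophil genes (2.50, 0.00232) upward. With an estimated correlation these 5 lists had adjusted p = 0.400 to 0.482. At the preset correlation the Kupffer cell call held (0.31, adjusted p = 0.0101), and those of lipogenesis (0.12, 0.832), male-biased genes (0.08, 0.191) and pericentral genes (-0.15, 0.340) ended. This fit compares 2 knockout arrays with 2. The arrays left out were chosen because they stood against the HGF contrast, so a larger HGF effect follows in part from that choice. The 2 remaining arrays with HGF also differed, at 0.32 (replicate 1) and 0.94 (replicate 3) on the response index over all tested probe sets.

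Clock genes differed between knockout arrays. Dbp, a transcription factor whose level follows the daily cycle, was at 10.72, 2.92 and 10.72 in knockouts without HGF (replicates 1 to 3), at 5.09, 11.05 and 2.81 in knockouts with HGF and at 2.61 to 7.50 in the 6 controls. Arntl was at 2.77, 5.76 and 2.59, at 5.66, 2.82 and 5.41, and at 4.84 to 5.62 in the controls. As a list of 12 genes, the circadian genes were called in none of the 6 contrasts.

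**Figure D3:**
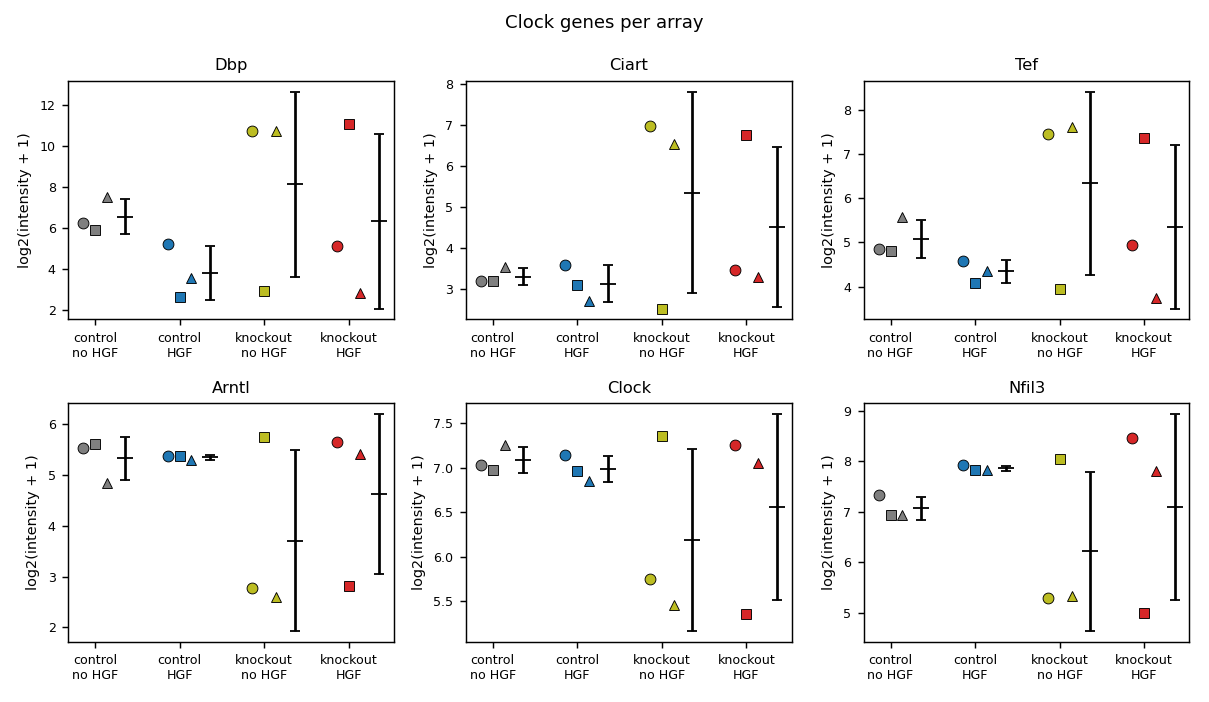
Log2(intensity + 1) of the clock genes Dbp, Ciart, Tef, Arntl, Clock and Nfil3 on each array, by group. Points are arrays, the marker gives the replicate number, and bars are means with SD (n = 3); Dbp lies at 10.72 to 11.05 on knockout replicates 1 and 3 without HGF and replicate 2 with HGF, against 2.61 to 7.50 in controls.

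Knockout livers without HGF differed from control livers without HGF most clearly in Rad51b, a gene with a part in DNA repair. Rad51b was 3.45 higher (SE 0.24, limma adjusted p = 0.000289). Its control arrays (2.67 to 3.39 with and without HGF) lay below the filter floor of 4, so the size depends on the offset, from 2.21 with an offset of 16 to 3.61 with none, and no linear fold is given. Rai14 (-0.96, SE 0.13) and the topoisomerase gene Top3b (-0.81, SE 0.11) were lower, both with adjusted p = 0.0438; both genes also fell with HGF in controls, a contrast that uses the same control arrays without HGF. These were the 3 genes called, 1 up and 2 down, and 1 probe set without a gene symbol, Entrez Gene 20519 by its identifier, was 1.77 higher (adjusted p = 0.0438). Among genes not past the threshold were Csrp2 (0.89, adjusted p = 0.0623), Nup93 (-0.83, 0.0625), Mgp (1.68, 0.0809), Plk3 (3.37, 0.0848) and the proline catabolism gene Prodh (0.95, 0.0848).

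Pericentral genes, which mark hepatocytes around the central vein, were shifted up in this comparison. All 11 of 11 were positive, with a median of 0.36 (camera adjusted p = 6.0e-07; adjusted p = 0.0685 with an estimated correlation). Adjusted over the list alone, 5 were higher, among them the glutamate transporter gene Slc1a2 (1.43) and the glutamine synthetase gene Glul (0.52). Periportal genes were shifted down (median -0.44, adjusted p = 0.0174), with 5 down over the list alone, among them the E-cadherin gene Cdh1 (-1.25) and Hal (-0.60), and 1 up, Pck1 (0.60). Matrix and stellate cell genes had a median of 0.40 (adjusted p = 8.7e-05), with 5 up over the list alone, among them Vim (0.89), Col3a1 (0.86) and Acta2 (0.82). Immediate early genes (0.85, adjusted p = 8.7e-05), NF-kappaB targets (1.38, adjusted p = 0.000518), glucocorticoid and stress genes (0.67, adjusted p = 0.00262) and female-biased genes (0.91, adjusted p = 0.0109) were shifted up. Kupffer cell genes (-0.48, adjusted p = 0.00175) and male-biased genes (-0.34, adjusted p = 0.0200) were shifted down. Without knockout replicate 2 without HGF, the array at 0.98 on the response index, the medians were 0.16 for immediate early genes, 0.06 for NF-kappaB targets and 0.42 for glucocorticoid and stress genes, and all 3 calls ended, as they did without both knockout replicate 2 arrays. Female-biased genes were then at 1.58, and at 0.55 without knockout replicate 1, 0.48 without knockout replicate 3 and 0.54 without control replicate 3, all without HGF. The Kupffer cell call ended without replicate 1 of the controls (-0.34) or the knockouts (-0.37), both without HGF. Also without arrays of the groups without HGF, the male-biased call ended without control replicate 2 (-0.23) or 3 (-0.30) or knockout replicate 1 (-0.30) or 3 (-0.33), and the periportal call without control replicate 3 (-0.42). With an estimated correlation none of the lists was called, with adjusted p = 0.148 for matrix genes and 0.391 to 0.573 for the other lists apart from pericentral genes.

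Settings moved the count of 3 to between 1 and 8 genes, except for 605 with array weights and 172 (93 up, 79 down) without both knockout replicate 2 arrays. Among the 172 were the clock genes Usp2 (5.46), Dbp (4.18), Ciart (3.47) and Arntl (-2.65). With camera at its preset correlation, interferon targets (-0.45, adjusted p = 0.00536), acute phase genes (-0.26, 0.0308) and heat shock genes (-0.27, 0.0461) were then called as lists. The count was 1 without control replicate 1 or 3 without HGF, control replicate 2 or 3 with HGF, knockout replicate 3 without HGF or knockout replicate 2 with HGF. It was 7 without control replicate 1 or knockout replicate 1 with HGF and 8 without knockout replicate 2 without HGF. Rad51b was called under every setting run.

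With HGF, knockout livers again had higher Rad51b than control livers, by 3.57 (SE 0.24, limma adjusted p = 0.000207; 2.24 with an offset of 16). It was the 1 gene called, with 612 tested genes with a symbol at an unadjusted p under 0.05. Cd59a, which protects cells from complement, was at 1.14 (adjusted p = 0.337), and the glutathione transferase genes Gstm3 and Gstm6 were at 1.45 (0.381) and 0.84 (0.337), none past the threshold. Sugct was at 1.19, Nme6 at 0.85 and L3hypdh at -1.09, each with an adjusted p of 0.381.

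Several lists that had shifted up with HGF in controls, whose arrays with HGF also enter this contrast, were lower in knockouts with HGF. NF-kappaB targets were shifted by a median of -1.99 (16 of 16 negative, adjusted p = 8.6e-10), immediate early genes by -1.27 (17 of 18 negative, adjusted p = 8.9e-08) and interferon targets by -0.98 (adjusted p = 2.1e-07). Acute phase genes were shifted by -0.64 (22 of 24 negative, adjusted p = 2.5e-06) and neutrophil genes by -2.12 (4 of 4 negative, adjusted p = 0.0120). Survival (-0.28, adjusted p = 0.0413) and cytoskeleton genes (-0.17, adjusted p = 0.0177) were also shifted down. Pericentral genes (0.39, 10 of 11 positive, adjusted p = 5.0e-06), sinusoidal endothelial genes (0.43, adjusted p = 0.000133), sterol synthesis (0.47, adjusted p = 0.0177) and xenobiotic genes (0.33, adjusted p = 0.0177) were shifted up. Over the list alone, Atf3 was lower (-2.11), 6 pericentral genes were higher, among them Slc1a2 (1.36) and Lect2 (0.70), 5 endothelial genes were higher and Lyve1 lower (-2.29), and Cyp2c55 was higher (1.81). With an estimated correlation none of these lists was called, with adjusted p = 0.144 for pericentral genes, 0.353 for endothelial genes and 0.475 to 0.550 for the others. Without knockout replicate 2 with HGF, the array at 0.02 on the response index, the medians were -0.15 for survival, -0.12 for cytoskeleton and -1.14 for neutrophil genes, and these 3 calls ended. Immediate early genes were then at -0.75, interferon targets at -0.58 and acute phase genes at -0.23. Without knockout replicate 3 with HGF, NF-kappaB targets were at -2.99 and acute phase genes at -1.10, and without control replicate 1 with HGF, endothelial genes were at 0.27 and cytoskeleton genes at -0.26. Without both knockout replicate 2 arrays and at the preset correlation, the neutrophil call held (adjusted p = 0.0404), the survival (0.134) and cytoskeleton (0.150) calls ended and fat oxidation genes were called (0.12, 0.0480). The survival call also ended without control replicate 1 (-0.25) or 2 (-0.26) or knockout replicate 1 (-0.15) with HGF or knockout replicate 2 or 3 without HGF (-0.28), and the cytoskeleton call without control replicate 2 (-0.09) or 3 (-0.15) with HGF. Sterol synthesis went to -0.11 without control replicate 1 with HGF and to 0.74 without control replicate 3 with HGF, and its call also ended without knockout replicate 3 with HGF (0.47). The xenobiotic call ended without control replicate 3 (0.28), knockout replicate 1 (0.19) or knockout replicate 3 (0.33), all with HGF. The count of 1 gene was 2 without control replicate 1 or knockout replicate 2, both with HGF, and 282 with array weights; without both knockout replicate 2 arrays it stayed at 1.

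Averaged over both conditions, Rad51b was 3.51 higher in knockout livers (SE 0.17, limma adjusted p = 7.8e-06; 2.22 with an offset of 16 and 3.68 with none, as the controls lay below the filter floor). All 6 knockout arrays (6.21 to 7.10) lay above all 6 control arrays (2.67 to 3.39). It was the 1 gene called, with 600 tested genes with a symbol at an unadjusted p under 0.05. Not past the threshold were L3hypdh (-1.18, adjusted p = 0.0787), Slc1a2 (1.39, 0.0961), Serpina11 (-1.04, 0.0961), Cd59a (0.82, 0.0961), Nup93 (-0.56, 0.0961), the interferon-induced gene Ifi27 (-0.59, 0.111) and Mgp (1.11, 0.119).

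Pericentral genes formed the list with the smallest p for the averaged knockout effect: 10 of 11 were higher in knockouts, with a median of 0.38 (camera adjusted p = 4.7e-10, and adjusted p = 0.0221 with an estimated correlation). Without both knockout replicate 2 arrays the median was 0.41 and camera called the list at its preset correlation (adjusted p = 2.8e-07), but not with an estimated correlation (adjusted p = 0.0699). Adjusted over the list alone, 8 rose: Slc1a2 (1.39), Oat (0.66), Lect2 (0.53), Aldh3a2 (0.43), the vitamin C synthesis gene Gulo (0.40), Glul (0.38), Cyp1a2 (0.35) and Rgn (0.24). Periportal genes were shifted down (median -0.20, 7 of 8 negative, adjusted p = 0.0149; Cdh1 -0.75 and Hal -0.34 over the list alone). Interferon targets were shifted down (-0.52, 16 of 17 negative, adjusted p = 0.000111; Rsad2 -1.53 and Irf7 -0.72 over the list alone). So were Kupffer cell genes (-0.26, 15 of 16 negative, adjusted p = 0.00420) and acute phase genes (-0.28, 21 of 24 negative, adjusted p = 0.0169). With an estimated correlation the periportal list had adjusted p = 0.468, interferon and Kupffer cell lists adjusted p = 0.738 and the acute phase list adjusted p = 0.742. Interferon targets were at -0.28 without knockout replicate 3 without HGF and at -0.26 without knockout replicate 2 with HGF. Without both knockout replicate 2 arrays, the Kupffer cell call ended (-0.20, adjusted p = 0.0648). At the preset correlation, NF-kappaB targets (-0.85, 0.000184), immediate early genes (-0.44, 0.0272) and cytoskeleton genes (-0.14, 0.0431) were then called as lower, against -0.64 (0.0971), -0.28 (0.382) and -0.12 (0.240) with all arrays.

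Matrix and stellate cell genes (median 0.28, adjusted p = 0.0126; Acta2 0.68, Lum 0.75 and Vim 0.47 over the list alone) and female-biased genes (0.59, 5 of 5 positive, adjusted p = 0.0113) were shifted up in the averaged knockout effect. So were fat oxidation genes (0.10, 13 of 16 positive, adjusted p = 0.0183; Cyp4a10 0.52 over the list alone) and sinusoidal endothelial genes (0.14, 11 of 12 positive, adjusted p = 0.0183). These 4 lists had adjusted p = 0.468, 0.468, 0.514 and 0.514 with an estimated correlation. Each of these 4 calls except that of female-biased genes ended without knockout replicate 2 without HGF (matrix 0.28, fat oxidation 0.10, endothelium 0.19), and without both knockout replicate 2 arrays, with adjusted p = 0.0691 for the 3 lists. The matrix median was 0.17 without control replicate 2 without HGF, and the endothelial median 0.23 without knockout replicate 3 with HGF. The fat oxidation call also ended without control replicate 1 without HGF (0.08) or 3 with HGF (0.12) or knockout replicate 1 (0.10) or 3 (0.12) with HGF. The endothelial call also ended without replicate 1 of the controls (0.11) or the knockouts (0.12) with HGF. The acute phase call ended without replicate 1 of the controls without HGF (-0.21) or with HGF (-0.26), and without knockout replicate 1 (-0.19) or 3 (-0.10) without HGF or 2 with HGF (-0.06), and its median was -0.47 without knockout replicate 2 without HGF. The Kupffer cell call ended without control replicate 1 without HGF (-0.19), and the periportal call without control replicate 1 (-0.21) or knockout replicate 3 (-0.16), both with HGF. NRF2 genes were not called as a list (median -0.06, adjusted p = 0.362), but 4 rose over the list alone, Nqo1 (0.94), Gsta2 (0.86), Gstm3 (0.63) and Gsta4 (0.45). The count of 1 became 54 (30 up, 24 down) without both knockout replicate 2 arrays, 552 with array weights, 17 with a random block and 2 with an offset of 16. It was 2 without control replicate 2 without HGF or knockout replicate 2 with HGF, 5 without control replicate 1 with HGF and 9 without knockout replicate 2 without HGF.

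**Figure D4:**
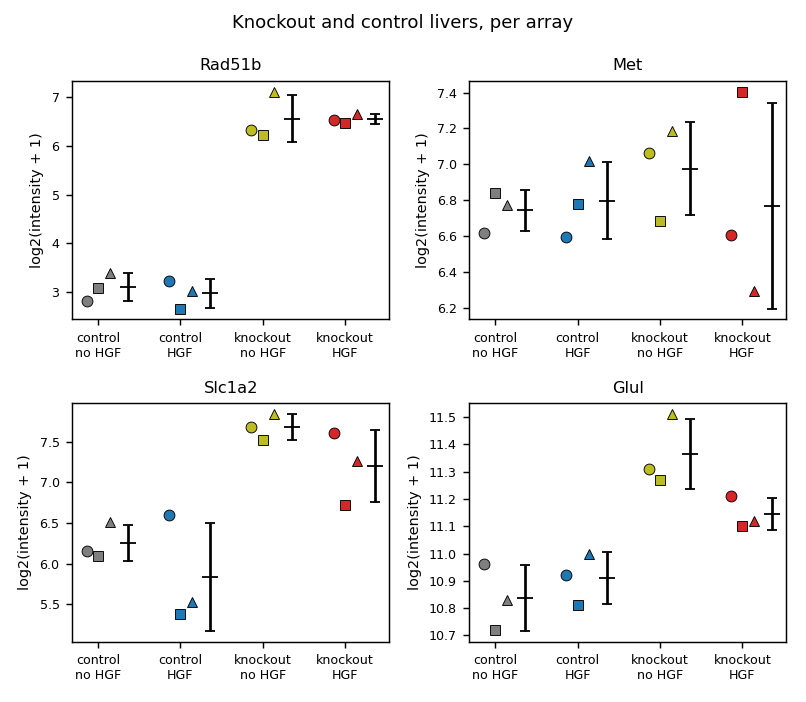
Log2(intensity + 1) of Rad51b, Met, Slc1a2 and Glul on each array, by group. Points are arrays, the marker gives the replicate number, and bars are means with SD (n = 3); Rad51b lies at 6.21 to 7.10 on the 6 knockout arrays against 2.67 to 3.39 on the 6 control arrays, while Met lies between 6.29 and 7.40 on all 12.

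The interaction, the HGF effect in knockout livers minus that in control livers, asks whether the response needs Met in hepatocytes. NF-kappaB targets had a median interaction of -3.48 (16 of 16 negative, camera adjusted p = 6.9e-12) and immediate early genes of -1.49 (17 of 18 negative, adjusted p = 1.8e-11; 11 down over the list alone). These lists had adjusted p = 0.310 and 0.270 with an estimated correlation, and NF-kappaB targets were at -2.23 without knockout replicate 2 without HGF. Among the 11 were Gadd45g (-6.72), Gadd45b (-4.54), Ier3 (-4.51), Junb (-3.33) and Atf3 (-2.72). Over their own lists, Phlda1 (-2.50) was also lower and G6pc (4.48) and Cyp2c55 (3.21) were higher.

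Limma called 0 genes for the interaction, with 694 tested genes with a symbol at an unadjusted p under 0.05 and a smallest adjusted p of 0.211. That value was shared by the genes of smallest p, among them Plk3 (-4.34, SE 0.82), Wwtr1 (-1.82, SE 0.27), a co-activator of the Hippo pathway, Klf7 (-1.55, SE 0.27) and Nme6 (1.27, SE 0.23). Others were Sertad2 (-1.21, SE 0.20), Csrp2 (-1.18, SE 0.19) and Top3b (0.85, SE 0.16). Array weights called 257 genes (150 up, 107 down), leaving out knockout replicate 1 without HGF or knockout replicate 3 with HGF called 1, and leaving out both knockout replicate 2 arrays called 23 (10 up, 13 down). Among the 23, Usp2 (-5.72), Ciart (-3.22) and Wee1 (-3.00) were lower, and Tubb2a (3.17), Arntl (2.83) and Nfil3 (2.04) higher. In that fit the medians were -1.59 for NF-kappaB targets (adjusted p = 2.1e-05) and -1.23 for immediate early genes (adjusted p = 2.0e-06), with adjusted p = 0.595 with an estimated correlation for both. Kupffer cell genes were called there (0.47, adjusted p = 0.0328, and 0.733 with an estimated correlation), against 0.38 (0.130) with all arrays, and 8 of 12 calls ended.

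Over the 27 genes called for HGF in either genotype, all of them in controls, the size of the HGF response in knockouts was a slope of 0.04 of that in controls (line through 0; Pearson's r across genes 0.226; 12 of 27 genes with the same sign). Genes are not independent replicates, so no p is given. The slope was 0.30 without knockout replicate 2 without HGF, 0.23 without knockout replicate 2 with HGF and -0.20 without knockout replicate 3 with HGF. Without both knockout replicate 2 arrays it was 0.56 over the 699 genes then called in either genotype (r 0.739). These arrays were chosen because they stood against the HGF contrast, so leaving them out favours a larger slope.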

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

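The tests of the exchanged labels, of RNA quality, of a missed dose, of the clock genes and of the neighbours of Rad51b were chosen only after the results they concern had been seen, but the counts over other splits of the arrays were planned. For 12 gene lists the HGF effect differed between control and knockout livers by the interaction test with camera at its preset correlation. With an estimated correlation none of the 12 passed.

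The median interaction, knockout minus control, was -3.48 for NF-kappaB targets and chemokines (adjusted p = 6.92e-12; median HGF effect 3.79 in controls and 0.08 in knockouts), -1.49 for immediate early genes (1.8e-11; 2.39 and 0.17) and -3.02 for neutrophil genes (0.0255; 3.39 and 0.39). It was -0.78 for acute phase genes (0.00025; 1.10 and 0.16), -1.08 for glucocorticoid and stress genes (0.000496; 1.68 and 0.28), -0.50 for interferon targets (0.00432; 0.80 and 0.26) and -0.52 for survival and apoptosis genes (0.00401; 0.49 and -0.05). It was -1.08 for ERK feedback genes (0.0427; 1.06 and -0.02), -0.94 for p53 and growth arrest genes (0.0431; 0.81 and -0.03) and -0.27 for matrix and stellate cell genes (0.00334; 0.18 and -0.08). It was positive for sinusoidal endothelial genes, at 0.46 (0.00336; -0.37 and 0.10), and for male-biased genes, at 0.47 (0.0149; -0.30 and 0.13). Adjusted p with an estimated correlation was 0.27 to 0.648 over the 12 lists.

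Without both knockout replicate 2 arrays, 8 of the 12 calls ended, and Kupffer cell genes were newly called (0.47, adjusted p = 0.0328, and 0.733 with an estimated correlation). Acute phase genes turned to 0.0495 (adjusted p = 0.808) and interferon targets to 0.12 (0.919). The medians of the others were -0.89 for neutrophil genes (0.694), -0.10 for survival genes (0.171), -0.50 for ERK feedback genes (0.169) and, each with adjusted p = 0.147, -0.50 for glucocorticoid and stress genes, -0.54 for p53 genes and -0.26 for matrix genes. The calls of NF-kappaB targets (-1.59), immediate early genes (-1.23), sinusoidal endothelial genes (0.38) and male-biased genes (0.84) held at the preset correlation, each with adjusted p = 0.595 with an estimated correlation. Single arrays also ended calls. Without knockout replicate 2 without HGF or with HGF, acute phase genes were at -0.22, interferon targets at -0.07 and -0.15, neutrophil genes at -1.87 and -2.04 and ERK feedback genes at -0.83 and -0.75, and all 4 calls ended. The neutrophil call also ended without control replicate 3 without HGF (-2.75) or 2 with HGF (-2.56), and the male-biased call without knockout replicate 3 without HGF (0.45) or with HGF (0.55). The ERK feedback call further ended without control replicate 3 with HGF (-1.13) or knockout replicate 1 without HGF (adjusted p = 0.0662) or 3 with HGF (-1.22). The p53 call ended without control replicate 1 (-0.98) or 3 (-0.96) or knockout replicate 3 (-1.06), all without HGF, or any knockout array with HGF (-1.09 to -0.85). Where calls held, the median was -0.28 for survival genes without knockout replicate 2 without HGF, -0.64 and -0.72 for glucocorticoid and stress genes without control replicate 1 and knockout replicate 2 with HGF, -0.51 for matrix genes without knockout replicate 3 without HGF and 0.73 and 0.74 for male-biased genes without knockout replicate 2 without and with HGF. For interferon targets it was -0.85 and -0.29 without control replicate 2 and 3 without HGF and -0.33 and -0.92 without knockout replicate 1 and 3 with HGF, and for acute phase genes -0.51 without control replicate 3 without HGF.

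The arrays of knockout replicate 2 stand with the opposite HGF group. The array labelled without HGF lay at 0.98 on the response index and the array labelled with HGF at 0.02. Poor RNA on these arrays is argued against by 1 measure only: 0 of the 2 lay outside the actin 3' to 5' log2 ratios of the other 10 arrays, with 0.973 and 0.937 against 0.873 to 0.989. That ratio was taken from normalized values. The array labelled without HGF also had the lowest median intensity of the 12 arrays, 6.75 in a range up to 7.03. An exchange of their labels may account for the pattern, but its test cannot decide. The test used 3310 genes that HGF moved by less than 0.2 in controls. Across them, the array labelled without HGF correlated at 0.645 with the HGF difference of knockout replicates 1 and 3. The array labelled with HGF correlated at -0.529. Both arrays had been picked for standing with the opposite group, and a state shared with that group for another reason would give such values too. A missed dose in one animal with a stray dose or stress in the other, and a variable response of livers without Met, both stay open: the clock index of the arrays labelled with and without HGF differed from the mean of replicates 1 and 3 of their groups by 1.78 and -2.19, but these replicates themselves differed by -1.89 with against without HGF.

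Clock genes set apart knockout replicates 1 and 3 without HGF and replicate 2 with HGF. On an index of the 6 clock genes that HGF moved by less than 0.5 in controls, a choice that narrows the control range, these arrays lay at 1.84, 1.73 and 1.68, against -0.04 to 0.17 in the controls; the other 3 of 6 knockout arrays lay within 0.25 above the highest control or lower, so the pattern is not one of every liver without Met. Over all 12 clock genes the 3 arrays lay at 2.16, 1.97 and 2.15, against -0.38 to 0.51 in the controls. Sampling at another phase of the daily cycle may account for it, but the labels give no time of day. In replicates 1 and 3 without HGF, 12 of 12 clock genes differed in the direction of that phase. Clock genes vary together, so any shift of the clock would give this count, which cannot single out the time of sampling. An effect of HGF or of the genotype on the clock in some of the knockout animals was not separated from the time of sampling. With the replicate 2 labels exchanged, the 3 arrays set apart would be the 3 knockouts without HGF. A pattern that follows HGF state among the knockouts therefore stays open.

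Rad51b stood higher on all 6 knockout arrays. A change of the whole chromosome region is argued against: the 10 nearest tested genes, 5 on each side, had a median averaged knockout effect of -0.01535 and a range of -0.29 to 0.11. A Cre transgene inserted in or near the gene, another difference in strain background carried with the transgene, and an effect of Met loss all stay open and were not tested. Array order follows genotype and cannot be told apart from it.

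For the averaged knockout effect, 4 of 100 splits of genotype within each HGF condition, the real one included, gave at least its 1 gene. The highest other split gave 3 genes, more than the real one. The share of splits is under 0.05, but it was not adjusted over the contrasts and rests on a count of 1. This count therefore does not exclude chance. For the HGF effect in controls (27 genes, highest other split 0) and the knockout effect without HGF (3 genes, highest other 0) and with HGF (1 gene, highest other 0), 1 of 10 splits reached the real count. These 10 splits are too few for a share under 0.05. For the HGF effect in knockouts (10 of 10 splits) and the interaction (100 of 100 splits) the real count was 0, which every split reaches, so these counts decide nothing about chance. Among their other splits the highest gave 1222 genes, in the split that exchanges the knockout replicate 2 arrays, and 1878 genes for the interaction, which points to a structure of the knockout arrays.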

How the results depend on the processing

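The fits without both knockout replicate 2 arrays and with no offset were chosen only after the data had been seen; all other settings were planned. Rad51b was called under every setting that gave a value in all 3 knockout contrasts, with an averaged effect from 2.22 with an offset of 16 to 3.68 with no offset. The pericentral shift of the averaged effect was called under each setting changed alone, with medians of 0.33 to 0.41; with both changes, an estimated correlation and no knockout replicate 2 arrays, it was not (adjusted p = 0.0699). Met was not called with no filter, with centred medians or after a further quantile normalization. Counts of genes below are against 27 for HGF in controls, 0 for HGF in knockouts, 3 for the knockout effect without HGF, 1 with HGF, 1 averaged and 0 for the interaction.

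With no filter, 13 genes were called for HGF in controls, where more genes share the adjustment, and 5 for the knockout effect without HGF. For the latter, a filter at log2 of 6 gave 1, an intensity trend with a robust prior 1, and the 2 groups alone 5. A 2-fold limit gave 1, a test against 1.2-fold 1, an offset of 16 gave 5 and leaving out the arrays with the letter A gave 1. For HGF in controls, the 2 groups alone gave 771, as the variable knockout groups no longer entered the spread, a test against 1.2-fold 0 and leaving out the letter A arrays 0. An offset of 16 gave 2 for the averaged effect. Array weights did not converge. For knockout replicates 1 to 3 they were 2.72, 0.24 and 0.45 without HGF and 2.83, 0.46 and 0.38 with HGF. Each knockout group thus rested mostly on replicate 1. These weights gave 1309 for HGF in controls and 257 for the interaction. For the knockout effect without HGF, with HGF and averaged, the weights gave 605, 282 and 552. Under them lipogenesis turned to -0.37 for the knockout effect with HGF and was at 0.11 for HGF in knockouts, where its test turned. The cause was not tested.

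Whether equal replicate numbers pair the arrays was not settled. Between the 2 control groups, deviations from the group mean correlated at 0.104, 0.177 and 0.050 for replicates 1 to 3. The closest partner had the same number for replicates 1 and 2 but not 3. Between the 2 knockout groups they correlated at 0.120, -0.829 and -0.698. There the replicate 2 arrays stand with the opposite HGF group, so pairing cannot be judged. A replicate block gave 0 for HGF in controls and 1 for the knockout effect without HGF; a random block gave 0, 1 and, for the averaged effect, 17.

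Without both knockout replicate 2 arrays, the counts were 526 for HGF in controls, 267 for HGF in knockouts, 172 and 54 for the knockout effect without HGF and averaged, and 23 for the interaction, and the response size was 0.56. Gadd45g turned to 2.57 for HGF in knockouts, acute phase and heat shock genes to -0.26 and -0.27 for the knockout effect without HGF, and acute phase and interferon genes to 0.0495 and 0.12 for the interaction. The cause was not tested beyond the weighing of these arrays. They were chosen by their place on the response index, so leaving them out favours calls for HGF in knockouts.

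With 1 array left out at a time, counts ranged from 0 to 305 for HGF in controls, 1 to 8 for the knockout effect without HGF, 1 to 2 with HGF, 1 to 9 averaged and 0 to 1 for the interaction. The response size ranged from -0.20 to 0.30. Medians for HGF in knockouts ranged from -0.92 to 1.66 for NF-kappaB targets and from -0.17 to 0.71 for interferon targets, the lowest without knockout replicate 3 with HGF. Medians for the knockout effect with HGF ranged from -0.11 to 0.74 for sterol synthesis and from -0.30 to 0.55 for lipogenesis, the lowest without control replicate 1 with HGF. Acute phase genes ranged from -0.26, without knockout replicate 2 without HGF, to 0.39 for the knockout effect without HGF. The cause was not tested.

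Among 186 list results, called or not, 55 calls ended with an estimated correlation. Only the pericentral call of the averaged knockout effect was left. Fry ended 47 calls and gave 2 further calls. Among 153 named gene results, array weights gave 59 further calls, leaving out both knockout replicate 2 arrays 37, and a replicate block ended 22 calls. A mean over probe sets and a test of every probe set were void, as each gene has 1 probe set. The response size has no value where fewer than 3 genes were called. Signal over background limits genes such as Hgf and Rad51b in controls, whose changes depend on the offset.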

Other observations

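The genes and fits in this part were chosen only after their values had been seen, and the fit on the 2 control groups alone was planned. In that fit, rises with HGF included those of the metallothionein gene Mt2 (8.86, SE 0.52), Tnfaip3 (7.83, SE 0.29), Cxcl2 (7.73), the chemokine gene Cxcl10 (7.32) and the pattern receptor gene Tlr2 (6.56). The feedback inhibitor gene Cish rose by 4.78 and the interleukin 1 antagonist gene Il1rn by 4.27. Falls included the lipolysis inhibitor gene G0s2 (-5.90), the glycogen targeting gene Ppp1r3c (-4.75), the nuclear receptor gene Nr0b2 (-4.20), G6pc (-3.65) and Cyp7a1 (-1.36). The hepatocyte transcription factor genes Foxa2 (-2.41), Hhex (-2.32) and Onecut1 (-2.06) also fell. This fit assumes nothing about the spread of the knockout arrays and has fewer arrays to estimate its own.

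On 49 genes, 25 higher and 24 lower in knockouts, all 6 knockout arrays lay outside the range of all 6 control arrays, which is 0.762% of tested genes against 0.216% by chance (13.9 genes). Besides Rad51b they included Cdc42ep5 (1.16), the T cell kinase gene Zap70 (1.02), the sulfatase gene Sulf2 (0.86), Gsta2 (0.86), Csad (-0.81), which takes part in taurine synthesis, Gstm2 (0.65), Sult1b1 (0.72) and Yap1 (-0.27). For the averaged knockout effect none of these except Rad51b passed limma over all genes. The 0.216% is an expected share. Genes vary together across these arrays and no other split was counted, so the excess over that share was not tested. Array order, which follows genotype, cannot be told apart from it.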
